A study of Homo sapiens with 3 samples.

How the data were processed

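The series holds 3 arrays, 1 for each of the DN, CD4 and CD8 populations of T cells, taken to groups by the source named in the labels. Per the labels' protocols, total RNA was isolated from the sorted cells with a column kit, labelled with biotin and hybridised to Affymetrix U133 Plus 2.0 arrays, and per the labels the RNA of each population was pooled. The method that turned scanned probes into 1 value per probe set is not given in the sources used here, and neither are its software and genome build, so no coordinates are given. The authors' deposited values are on a log2 scale, which was read from the values: they reach 14.77, which is 27896 on the linear scale at base 2 and fits a scanner maximum of 65535, while base e would give a linear value far above that maximum. They were already on a common scale when deposited, since the medians of the 3 arrays lay within 0.024 log2, below the 0.1 set as the limit for rescaling, and they were used as deposited. Of the 54675 probe sets, 27.1% carried an identical value on all 3 arrays. The reason is not given in the sources used here, and a difference of 0 is not a measure of precision.

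Probe sets were named through the platform's annotation, with symbols updated through Entrez identifiers for 99.9% of named probe sets. It gave a single gene for 41030 probe sets, several for 1801 and none for 11721. A further 62 control probe sets and 61 probe sets of sex-linked genes were left out of all comparisons. List members with no probe set of their own were not analysed here. A floor was set at the median of all values, 4.35, and values under it were raised to it for calls, counts, ranks and list medians. The difference of a single gene from a value under 5.20, the 90th percentile of the silent reference, was taken from that level and is given as at least that size, a reading added after the data were seen. No fold is given where both values lie under it. A gene counted as measured when its probe set exceeded the floor on at least 1 array. Each gene was represented by its probe set with the highest mean, leaving out probe sets that may cross-hybridise where another existed, which gave 11989 measured genes of 19739. Folds and counts are differences of these log2 values with a threshold of 2-fold.

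The comparisons were DN against both others, each pair of arrays, and the share of genes at which DN lay nearer to CD4 or CD8. With 1 array per group there is no test and no p-value. The error given is the SD of log2 differences between probe sets of the same gene, which covers differences between probes of these arrays and leaves out the spread between people or sorts. In a simulation of an unchanged DN array, each gene was placed at the mean of CD4 and CD8 with a deviation drawn from that disagreement. The steps were tested on simulated data of 11989 genes for DN against both others. Of genes changed by 1.5, 2 and 3 log2, 90.8%, 98.2% and 100% were recovered, and 1.18% of 11789 unchanged genes passed the threshold. Changed genes were drawn only from those more than 3 log2 above the floor, so recovery of dimmer genes was not tested. Shares have exact binomial (Clopper-Pearson) 95% intervals. Precision is limited by the number of arrays.

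The rules for floor, threshold, probe sets, gene lists and named genes were set before the data were examined. Named genes were the 12 with the greatest smaller difference among those at least 2-fold higher, and the 12 among those lower, on DN than on both others. For each pair of arrays they were the 6 highest and the 6 lowest. Genes at the floor on an array compared were ranked apart, up to 6 per direction. A gene with another probe set above the floor that differed by over 2-fold the opposite way was passed over, and variable segments of receptors and immunoglobulins were not named. Up to 4 members per list and comparison were named as well, with the sort markers.

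The 32 gene lists covered T cell identity, CD4 and CD8 lineage, naive and central memory, cytotoxic effector, NK receptors, MAIT and innate-like T, gamma-delta T, regulatory T, types 1, 2 and 17, homing receptors, cytokines and chemokines, inhibitory receptors and anergy, cell cycle, interferon response, immediate early and stress, apoptosis, TCR signalling, activation and class II, ribosomal proteins and oxidative phosphorylation. They also held markers of B cells, plasma cells, monocytes, neutrophils, dendritic cells, platelets, erythroid cells and NK cells, and a reference of genes silent in blood. A list's median was set against 10000 random lists of equal size drawn from the same 20 bins of mean expression, and its percentile describes these arrays only. Medians of random lists varied little, so a list median smaller than the disagreement between probe sets can reach an extreme percentile. Alternatives were floors at the 25th and 65th percentile of all values and at the 90th percentile of the silent reference, quantile normalization, centring on the median, the mean over probe sets, leaving out probe sets ending in _x_at, _s_at or _a_at, log2(value + floor), no floor and no filter, and a 3-fold threshold. The mean over probe sets was taken before the floor was applied and includes probe sets under the floor on all arrays. A smaller fold by that mean therefore need not come from probe sets that disagree. A restriction to genes with several probe sets that all passed the threshold was chosen after seeing the data. Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.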

Results

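Gene expression was measured in 3 populations of human T cells that carry the alpha-beta T cell receptor and lack CD25, the alpha chain of the interleukin-2 receptor. The populations were freshly sorted from the peripheral blood of healthy people into double-negative cells (DN), which lack both coreceptors CD4 and CD8, and into the conventional CD4 and CD8 populations. RNA of each population was pooled and hybridised to 1 Affymetrix U133 Plus 2.0 array per population, an oligonucleotide array that reads most human transcripts through sets of short probes near their 3′ end. There were no replicate arrays, so no difference below has a replicate check and no p-value is given. The number of donors in each pool is not stated in the labels. Each array gave 54675 probe-set values on a log2 scale, with medians of 4.37 (DN), 4.35 (CD4) and 4.34 (CD8), and 50.1%, 49.9% and 49.7% of them lay above the floor of 4.35. After selection of 1 probe set per gene, 11989 genes were measured on at least 1 array. Calls and counts use this floor. Values under 5.20, the level under which 90% of values of genes silent in blood lay, are not clearly above background, so the difference of a single gene from such a value is taken from 5.20 and given as at least that size. Probe sets of the same gene disagreed on a log2 difference with an SD of 0.39 for DN against CD4, 0.36 for DN against CD8 and 0.20 for CD4 against CD8 (14384 probe sets of 5379 genes), which is the only error available here.

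The coreceptor transcripts followed the sort for CD4 and lay between the other arrays for CD8. CD4, the coreceptor for class II molecules, stood at a log2 value of 10.47 on the CD4 array, 5.41 on the DN array and 4.63 on the CD8 array (probe set 203547_at). CD8A, the alpha chain of the coreceptor for class I molecules, stood at 11.32 on the DN array, against 9.55 on the CD4 array and 13.08 on the CD8 array (205758_at). CD8B, its beta chain, stood at 8.85, 6.19 and 10.95 on the DN, CD4 and CD8 arrays (215332_s_at), while the 1 probe set of CD8B above the floor that is not shared between transcripts passed the floor on CD8 only. DN therefore lay 3.37-fold below CD8 for CD8A and 4.31-fold below it for CD8B, and above CD4 by 3.41-fold and 6.32-fold. The CD3 chains of the receptor complex were similar on all arrays, at 12.36, 12.25 and 12.51 for CD3D and 10.47, 10.88 and 10.89 for CD3E. IL2RA, which encodes CD25, stayed below the floor on all 3 arrays at both of its probe sets.

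RNA quality differed between the arrays. The 3′ to 5′ ratio of the GAPDH control probe sets, which rises when transcripts are degraded or incompletely copied, was 24.6 on the DN array, against 4.63 on both the CD4 and the CD8 array. On a log2 scale, the ratio of the ACTB controls was 6.72 on DN, 5.13 on CD4 and 5.14 on CD8. GAPDH stood at log2 7.32 at its 5′ probe set on DN, against 9.85 on CD4 and 10.09 on CD8. The 18 spiked bacterial controls, added to each sample rather than made by the cells, differed by a mean of 0.05 log2 (SD 0.07) between DN and CD4.

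**Figure D1:**
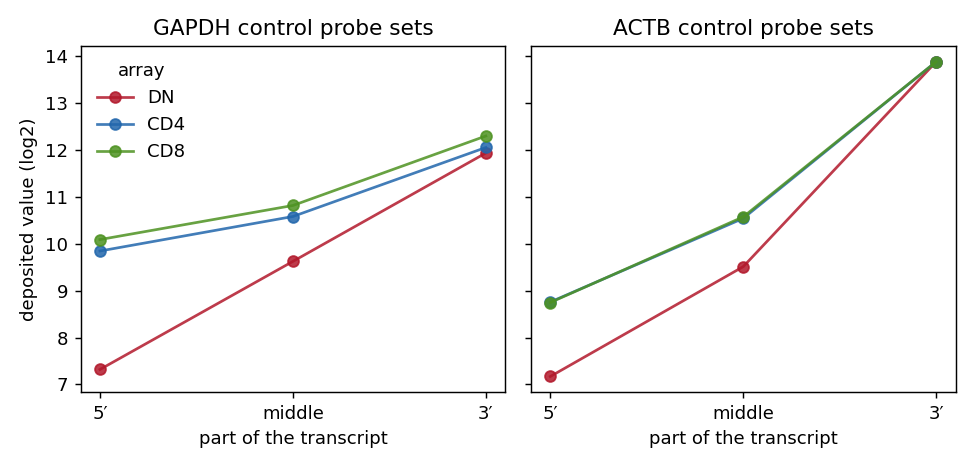
Deposited log2 value (vertical axis) of the GAPDH (left) and ACTB (right) control probe sets at the 5′ end, middle and 3′ end of each transcript, 1 point and 1 line per array. The GAPDH lines come together at the 3′ end and part at the 5′ end, where DN stands at 7.32 against 9.85 on CD4 and 10.09 on CD8.

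The first comparison asked what sets DN cells apart from both conventional populations. The genes with the greatest excess on the DN array included IGHM, IL1B, HAVCR2, FOSB and MYB. IGHM, the constant region of the IgM heavy chain, was at least 17.1-fold higher than on both CD4 and CD8 (212827_at). IL1B, an inflammatory cytokine made mostly by myeloid cells, was higher by 15.6-fold and at least 22.04-fold (39402_at). HAVCR2, the inhibitory receptor TIM-3, was higher by 10.1-fold and 14.0-fold (235458_at), and FOSB, a subunit of the AP-1 transcription factor, by at least 6.23-fold against both (202768_at). MYB, a transcription factor of progenitors and thymocytes, was one of the brightest of these genes, at log2 12.22 on DN against 9.39 on CD4 and 9.06 on CD8 (204798_at).

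In all, 217 genes were at least 2-fold higher on DN than on both other arrays and 65 were at least 2-fold lower. The counts were 77 higher and 162 lower for CD4, and 59 higher and 60 lower for CD8. Other genes of the B-cell lineage among the named ones were POU2AF1, a coactivator of octamer-binding factors, at 8.42-fold above CD4 and at least 55.8-fold above CD8, and JCHAIN, which joins IgM and IgA into polymers, at least 5.15-fold above both. Genes known from myeloid cells included CLEC5A, a lectin receptor, at 11.6-fold above CD4 and at least 14.6-fold above CD8. ITGAX, the integrin chain CD11c, was higher by 5.69-fold and at least 11.0-fold, and the chemokine CCL22 by 6.89-fold and 9.90-fold. DUSP6, a phosphatase that switches off ERK kinases, was higher by 5.55-fold and 11.99-fold. LGALS3, which encodes galectin-3, was higher by 6.74-fold and 5.50-fold. NIBAN3 was higher by 17.5-fold and 13.3-fold and BASP1 by 5.60-fold and at least 9.66-fold. LAYN, a hyaluronan receptor, was at least 12.2-fold above CD4 and 9.70-fold above CD8. SDC2, a syndecan, was 9.52-fold above CD4 and at least 15.4-fold above CD8. CAV1, the caveolae protein caveolin-1, was at least 5.29-fold and SMIM43 at least 4.67-fold above both. When the mean over a gene's probe sets was taken, at the floor of 4.35 as in all alternatives unless another is named, LAYN lay under 2-fold and other folds were smaller: 15.1 for IGHM against both, 4.69 and 5.27 for MYB, 2.36 and 2.504 for HAVCR2, 2.37 and 3.02 for BASP1, 2.39 and 3.70 for ITGAX, 2.60 and 2.34 for LGALS3, 3.14 and 5.57 for POU2AF1, 2.71 for NIBAN3, 3.55 for CAV1 and 4.49 for SDC2. Of these genes, only IGHM and HAVCR2 had another probe set whose mean over the arrays lay above the floor. For the others the mean took in probe sets near or under background, which can shrink a fold.

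Because both comparisons share the DN array, its chance deviations enter both counts. An unchanged DN array, simulated 100 times from the disagreement between probe sets around the mean of CD4 and CD8, gave a mean of 60.5 genes higher and 71.2 lower than both others. Independent lists would share 11.6 genes higher and 2.65 lower. The 217 genes higher on DN thus exceeded the simulated count and the 65 genes lower did not. The simulated error was taken from differences that include DN, on which probe sets disagreed more (SD 0.39 and 0.36) than between CD4 and CD8 (0.20). It came from genes with several probe sets and leaves out shifts shared by all probe sets of a gene. Whether the RNA quality of DN caused such shifts or the greater disagreement was not tested, so the excess over the simulation has no assigned cause. Of the other probe sets of these genes, 47.6% (40 of 84) were also at least 2-fold higher on DN than on both others, and 22.2% (8 of 36) were also at least 2-fold lower. The same shares were 55.1% and 37.0% for genes higher and lower on CD4, and 51.9% and 39.0% for CD8. With the floor at the 65th percentile of all values, 116 genes were higher and 42 lower on DN, and with the mean over a gene's probe sets 115 were higher.

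**Figure D2:**
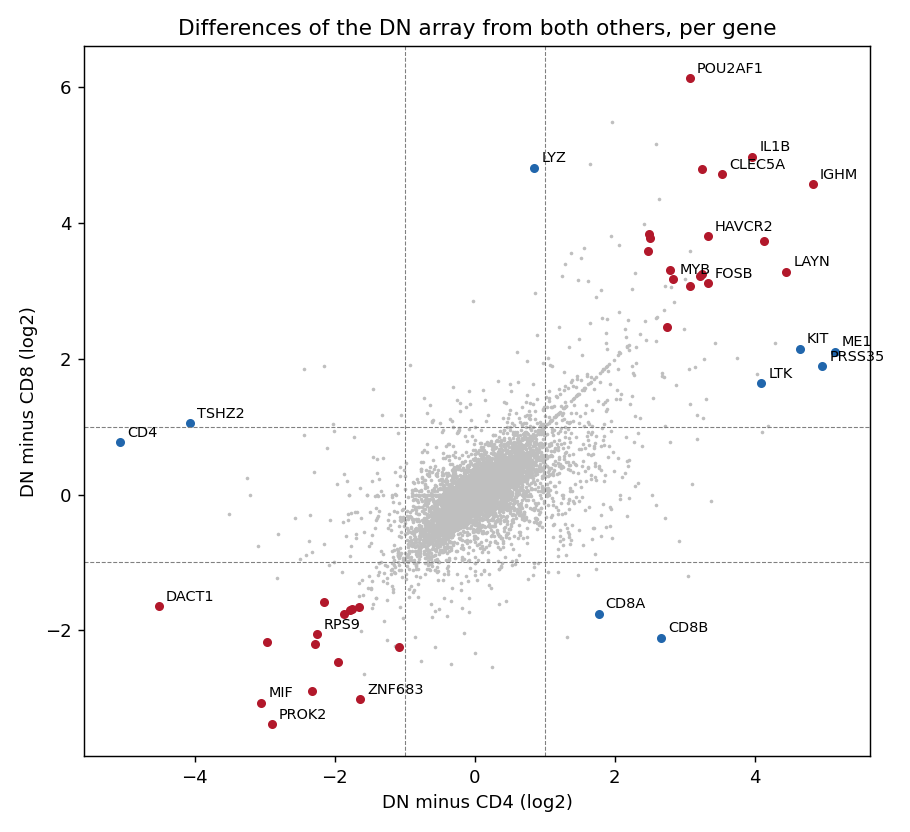
Log2 difference of DN from CD4 (horizontal axis) against log2 difference of DN from CD8 (vertical axis) for each of 11989 measured genes, with dashed lines at 2-fold, genes ranked highest or lowest in DN against both arrays in red and further named genes in blue, all after values under 4.35 were raised to it. IGHM, IL1B and POU2AF1 lie at the upper right, MIF and PROK2 at the lower left, and CD4 at the far left.

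Among genes lower on DN than on both others were MIF, a cytokine that acts on macrophages, and PROK2, a secreted prokineticin. MIF was at least 6.51-fold below CD4 and 6.56-fold below CD8 (217871_s_at), and PROK2 was 7.45-fold and 10.4-fold below them (232629_at). ATP5MC2, the ring subunit of the mitochondrial ATP synthase, was lower by 4.85-fold and 4.61-fold. RPS9, a ribosomal protein, was lower by 4.78-fold and 4.16-fold. CYBA, a subunit of the NADPH oxidase, was lower by at least 3.09-fold and 4.41-fold, and CD226, an activating adhesion receptor, by 3.36-fold and 3.20-fold. ZNF683, the transcription factor HOBIT of cytotoxic and tissue-resident lymphocytes, was lower by 3.10-fold and 8.08-fold. CACHD1 was lower by 7.78-fold and 4.49-fold and CLU by at least 2.34-fold and 2.18-fold. MIF-AS1, which lies antisense to MIF, was lower by 3.43-fold and 3.26-fold. The remaining named genes were DACT1, a regulator of Wnt signalling, lower than CD4 by at least 13.1-fold, GPR27, lower by at least 2.77-fold and 4.12-fold, DCBLD2, lower than CD4 by at least 2.46-fold, EPHX4, lower than CD8 by at least 2.63-fold, and C10orf95. Taken from 5.20, C10orf95 lay under 2-fold against both arrays (1.77-fold), as did DACT1 (1.79-fold) and DCBLD2 (1.66-fold) against CD8 and EPHX4 (1.17-fold) against CD4, so these calls rest on the lower floor. As this count did not exceed the simulated one, the genes cannot be separated by number alone from the disagreement between probe sets. With the mean over probe sets, ATP5MC2, CLU and DCBLD2 lay under 2-fold against both arrays and GPR27 against CD4, and the folds were 2.74 and 2.08 for CACHD1 and 2.19 and 2.04 for RPS9 and 2.33 and 3.38 for CYBA. CYBA lay under 2-fold against CD4, and CLU against CD8, without shared probe sets. With the floor at the 65th percentile, C10orf95, CLU and DCBLD2 lay under 2-fold against both and CYBA, GPR27, DACT1 and EPHX4 against at least 1 array.

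The next question was which conventional population DN resembled. Across all measured genes, the log2 differences had an SD of 0.53 between DN and CD4, 0.47 between DN and CD8 and 0.41 between CD4 and CD8. Of the 283 genes at least 2-fold higher on CD8 than on CD4, DN lay nearer to CD8 at 202, or 71.4% (exact binomial 95% interval 65.7% to 76.6%). Of the 165 genes higher on CD4 than on CD8, DN lay nearer to CD4 at 71, or 43.0% (35.4% to 51.0%). These intervals cover the number of genes only, and genes are not independent replicates.

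Against CD4, the DN array was higher for genes of CD8 and natural killer (NK) lymphocytes and of innate-like T cells, and lower for genes typical of CD4 cells. ME1, a malic enzyme that makes NADPH, was at least 19.6-fold higher on DN (204059_s_at), and KIT, the receptor for stem cell factor, at least 13.9-fold higher (205051_s_at). LTK, a receptor tyrosine kinase, was at least 9.48-fold higher (207106_s_at). CD4 itself was 33.5-fold lower on DN, and TSHZ2, a zinc-finger gene of CD4 cells, was 16.7-fold lower (238577_s_at). In total 464 genes were at least 2-fold higher on DN and 195 lower, against 167 and 155 for the simulated unchanged array. The higher count was 267 with the floor at the 65th percentile and 254 with the mean over probe sets. Beside IGHM and NIBAN3, the other genes with the greatest excess on DN were FLT4, a receptor for vascular endothelial growth factors, at no less than 11.5-fold, DKK3, a Dickkopf-family secreted protein, at 17.2-fold, and the collagen chain COL5A3 at 16.4-fold. PRSS35 was at least 17.4-fold, LAYN at least 12.2-fold, DBN1, an actin-binding protein, at least 10.1-fold and COL5A1, another collagen chain, at least 6.02-fold higher. Lower on DN were DACT1 by at least 13.1-fold, the hydrolase FHIT by 11.4-fold, the protease CTSL by at least 8.58-fold and NET1 by 8.55-fold. ANKRD55 was lower by at least 5.14-fold and the phosphodiesterase PDE7B by at least 3.27-fold. ST6GALNAC1 and GOLGA7B passed 2-fold at the lower floor only, with 1.93-fold and 1.70-fold from 5.20. With the mean over probe sets, DKK3 was 5.95-fold, ME1 4.77-fold, FLT4 3.23-fold and NIBAN3 2.71-fold higher. By that mean, DBN1 was 6.22-fold, COL5A1 4.62-fold and LTK 5.75-fold higher, and TSHZ2 6.63-fold and CD4 4.37-fold lower. The other probe set of CD4 stood at 2.48 on all 3 arrays, under the floor. Without shared probe sets, DKK3 was 2.37-fold and ME1 8.24-fold higher and TSHZ2 6.80-fold lower. PDE7B lay under 2-fold with the mean over probe sets and at the 65th-percentile floor.

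By gene list, 6 of 9 measured CD8 lineage genes were at least 2-fold higher on DN than on CD4 and none lower, with a median log2 difference of 1.497 (percentile 100 among 10000 random lists matched on expression, as a description of these arrays). CRTAM, a receptor of activated cytotoxic cells, was higher by 2.59 log2 and LAG3, an inhibitory receptor for class II molecules, by 1.54. Of 12 CD4 lineage genes, 6 were lower and none higher (median -1.03, percentile 0), including FBLN7 at -2.43 and the costimulatory receptor ICOS at -1.14. Of 19 NK receptors, 11 were higher and none lower (median 1.22, percentile 100). KLRC4 was higher by at least 2.19 log2, KLRC3 by 2.92, and the signalling adaptors TYROBP and FCER1G by 2.15 and 2.08. Of 17 genes of mucosal-associated invariant T (MAIT) and other innate-like T cells, 11 were higher, or 9 at a floor of 5.20, and none lower (median 1.30, percentile 100), among them CEBPD at 3.18, the efflux pump ABCB1 at 2.21 and CXCR6 at 2.20. Cytotoxic effector genes did not move as a group by that threshold: 2 of 22 were higher, CTSW at 1.67 and GZMK at 1.58, and 2 were lower, ZNF683 at -1.63 and GNLY at -1.25 (median 0.17, percentile 99.67). Of 12 inhibitory receptors and anergy genes, 6 were higher and 2 lower (median 0.71, percentile 100), with EGR3 higher by at least 1.38, CD244 by 1.73 and TIGIT by 1.72, and BTLA at -1.69.

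Against CD8, the DN array was higher for monocyte markers and lower for cytotoxic effector genes. POU2AF1 was at least 55.8-fold higher on DN (205267_at) and CYP1B1, a cytochrome P450, at least 29.8-fold higher (202437_s_at). LYZ, the lysozyme of monocytes and granulocytes, was 28.1-fold higher (213975_s_at), and S100A8, a calcium-binding protein of the same cells, at least 16.1-fold higher (202917_s_at). GZMB, a granzyme of killer cells, was 4.73-fold lower on DN, GNLY, which encodes the pore-forming granulysin, 4.40-fold lower and GZMH 4.27-fold lower. In total 299 genes were at least 2-fold higher on DN and 163 lower, against 132.9 and 192.5 for the simulated unchanged array. These simulated counts again hold differences between CD4 and CD8. The lower count was under the simulated one, but this does not show whether it exceeds error alone. The higher count was 164 with the floor at the 65th percentile and 162 with the mean over probe sets, and the lower one 104 with log2(value + floor). Beside IL1B and IGHM, C5AR1, the receptor for complement C5a, was at least 12.4-fold higher. PLA2G7, a secreted phospholipase of macrophages, was at least 19.8-fold, SDC2 at least 15.4-fold, CLEC5A at least 14.6-fold, the cystine transporter SLC7A11 at least 11.3-fold and TNFAIP2 at least 6.88-fold higher. Lower on DN were PROK2 by 10.4-fold, MIF by at least 6.56-fold, ZNF683 by 8.08-fold, the non-coding LINC01943 by at least 5.96-fold, S100B by at least 3.81-fold and the adhesion molecule NRCAM by at least 4.34-fold. GPR27 was lower by at least 4.12-fold, the guidance receptor ROBO1 by at least 2.79-fold and EPHX4 by at least 2.63-fold. DCBLD2, LRRN1 and ADRB1, a beta-adrenergic receptor, passed 2-fold at the lower floor only, with 1.66-fold, 1.25-fold and 1.21-fold from 5.20. With the mean over probe sets, S100B and TNFAIP2 lay under 2-fold, CYP1B1 was 10.5-fold, LYZ 7.16-fold, POU2AF1 5.57-fold, SDC2 4.49-fold and SLC7A11 4.62-fold higher, and GPR27 was 2.12-fold lower. ROBO1 and EPHX4 lay under 2-fold or gave no value at the 65th-percentile floor.

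Of 22 cytotoxic effector genes, 12 were at least 2-fold lower on DN than on CD8 and none higher (median -1.05, percentile 0). NK receptors were also lower on balance, with 6 of 19 lower (4 at a floor of 5.20) and 1 higher (median -0.61, percentile 0, and -0.13 without probe sets shared between transcripts). KLRD1, the CD94 receptor chain, stood at -2.10, KLRC4 at -1.20 and CD300A at -1.17, and FCER1G was the one gene higher, at 1.48. The 9 CD8 lineage genes had a median of -0.17 (percentile 4.18), with CD8A and CD8B the only ones past 2-fold and LAG3 at -0.74. CD4 lineage genes were slightly higher on DN (median 0.44, percentile 99.96, and 0.0044 with the mean over probe sets), with FBLN7 at 1.08 or more, CTLA4 at 1.59 and TSHZ2 at 1.05 the 3 of 12 past 2-fold. MAIT and innate-like genes were higher on DN here too, in 5 of 17, or 4 at a floor of 5.20, with none lower (median 0.71, percentile 100). ME1 was higher by 2.10 log2, LTK by 1.64 and the chemokine receptor CCR6 by 1.60, while IL23R, which binds interleukin-23, passed 2-fold at the lower floor only. Genes of type 17 cells, of which CCR6 and IL23R are also on the innate-like list, were higher in 4 of 7 against CD8 (median 1.17, percentile 100) and in 4 of 7 against CD4 (median 1.23, percentile 100), or in 2 and 3 at a floor of 5.20. CTSH, a cathepsin, was higher by 1.23 log2 against CD4 and 1.30 against CD8, and CCL20 by at least 1.06 against CD4.

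Immediate early and stress genes, which respond within minutes to stimulation or handling, were higher on DN than on both others. Of 14 measured, 7 were at least 2-fold higher than on CD4 (median 0.85, percentile 100) and 6 than on CD8 (median 0.67, percentile 100), and none was lower in either comparison. At a floor of 5.20 these were 5 and 4. EGR1 was higher by 2.70 and 1.73 log2, DUSP1 by 1.88 and 1.26, and JUN by 1.63 and 1.03, while FOS passed 2-fold at the lower floor only. Regulatory T cell genes were higher in 3 of 10 against CD4 (median 0.42, percentile 99.91) and in 4 of 10 against CD8 (median 0.52, percentile 100). IKZF2, the transcription factor Helios, was higher by 3.27 and 1.12, and RTKN2 by 1.07 and 1.53. FOXP3, the defining factor of these cells, lay under 5.20 on all 3 arrays, as did TNFRSF18 and TNFRSF9, and CTLA4 lay at -0.31 against CD4. T cell identity genes were slightly lower, with medians of -0.16 against CD4 (percentile 2.44) and -0.16 against CD8 (percentile 1.64). CD7 was lower in both, at -1.62 and -1.26, and THEMIS, a regulator of thymic selection, lay at -1.17 against CD8.

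Markers of other blood cells moved with these groups. Of 13 measured monocyte markers, 5 were at least 2-fold higher on DN than on CD4 (median 0.85, percentile 100) and 7 than on CD8 (median 1.14, percentile 100), with none lower. At a floor of 5.20 the counts were 2 and 3 and the medians 0.46 and 0.46. S100A12 was higher by at least 1.71 log2 against both arrays, and CD14 passed 2-fold at the lower floor only. Of 13 B-cell markers, 4 were higher against each array (medians 0.25 and 0.25, percentiles 98.2 and 99.0) and none lower, or 2 at a floor of 5.20. MS4A1, which encodes CD20, was higher by 3.08 and 1.33 log2, while TCL1A and the lectin CD22 passed 2-fold at the lower floor only. JCHAIN was the only measured one of 7 plasma cell markers. IRF8, 1 of 2 measured dendritic cell markers, was higher than on CD8 by 1.96, and MMP9, 1 of 2 measured neutrophil markers, was higher by at least 1.47 against both arrays. Of 4 platelet markers, CLU was lower against both and the others lay within 2-fold, and no erythroid marker was above the floor. Of 7 NK-cell markers, all of which are also on the NK receptor or innate-like lists, 4 were higher against CD4 (median 1.81, percentile 100). Against CD8, 1 was higher and 1 lower (median 0.28, percentile 97.34).

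**Figure D3:**
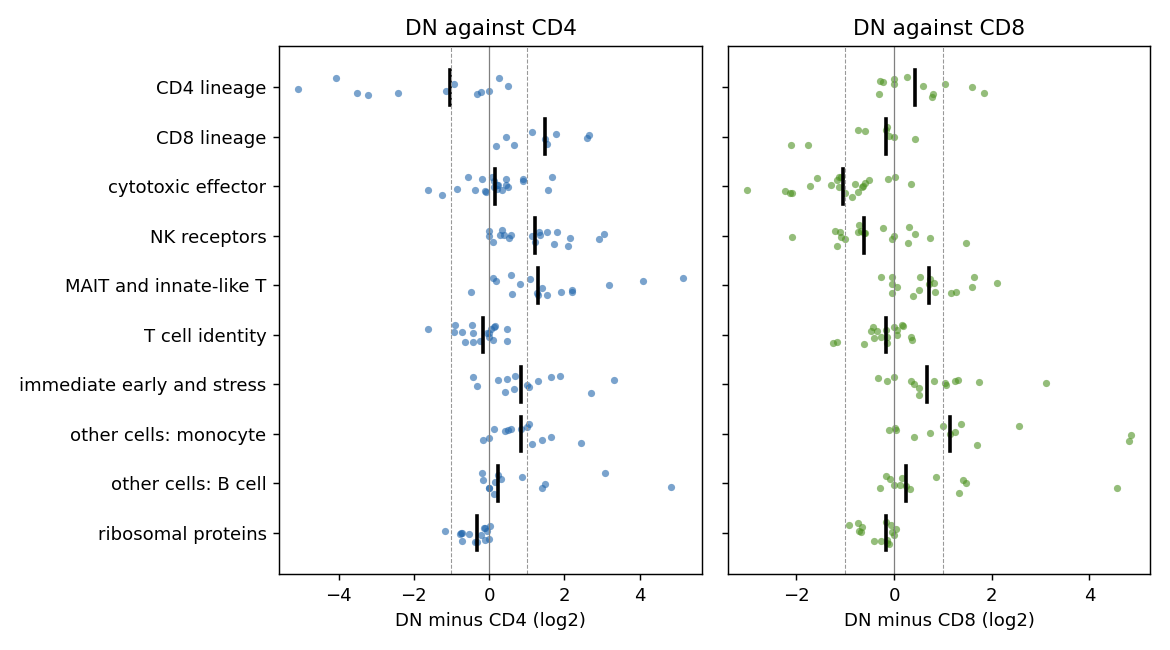
Log2 difference of DN from CD4 (left) and from CD8 (right) for each measured gene of 10 gene lists, 1 point per gene, with the list's median as a black bar and dashed lines at 2-fold, all after values under 4.35 were raised to it. NK receptors have a median of 1.22 against CD4 and -0.61 against CD8, and the MAIT and innate-like genes 1.30 and 0.71.

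The conventional populations differed from each other by their lineage genes. CD4 was at least 38.7-fold higher on the CD4 array than on CD8, TSHZ2 34.7-fold and FBLN7 at least 11.4-fold (229247_at). CD8B was 27.3-fold higher on CD8 and CD8A 11.5-fold. The lectin-like NK receptors KLRC4, KLRC3 and KLRD1 were higher on CD8 by at least 10.5-fold, by 12.1-fold and by 10.7-fold. With the mean over probe sets, CD4 was 4.37-fold and TSHZ2 6.63-fold higher on CD4 and CD8B 10.1-fold higher on CD8, and without shared probe sets TSHZ2 was 8.21-fold higher and CD8B 5.28-fold lower on CD4. In total 165 genes were at least 2-fold higher on CD4 and 283 higher on CD8, or 102 and 186 with the floor at the 65th percentile and 95 and 171 with the mean over probe sets. Of 12 CD4 lineage genes, 7 were higher on CD4 (median 1.52, percentile 100), and of 9 CD8 lineage genes, 6 were higher on CD8 (median -1.59, percentile 0). Cytotoxic effector genes were higher on CD8 in 14 of 22 (median -1.23, percentile 0), with CTSW at -2.33 and NKG7 at -2.02. NK receptors were higher on CD8 in 12 of 19, or 10 at a floor of 5.20 (median -1.40, percentile 0) and MAIT and innate-like genes in 6 of 17 (median -0.63, percentile 0). Genes of the naive and central memory state were slightly higher on CD4 (median 0.34, percentile 100), with 1 of 19 past 2-fold in each direction, MAL at 1.06 and PECAM1 at -1.31.

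Of 13 monocyte markers, 2 were at least 2-fold higher on CD4 than on CD8, LYZ and S100A8, and none was lower (median 0.12, percentile 99.64). LYZ was 15.6-fold, CYP1B1 at least 7.63-fold, S100A8 at least 5.16-fold, PLA2G7 at least 3.27-fold and MPEG1, a macrophage perforin, at least 2.4996-fold higher. CTSL was at least 8.58-fold higher on CD4, the leukotriene receptor CYSLTR1 at least 9.14-fold, ANKRD55 at least 5.14-fold and coagulation factor F5 at least 4.46-fold. Higher on CD8 were DKK3 by 9.12-fold, DBN1 by at least 5.04-fold, PRSS35 by at least 4.69-fold, ME1 by at least 4.57-fold, S100B by at least 3.81-fold and the phospholipase PLCG2 by at least 3.20-fold. TMT1A was 11.1-fold higher on CD8 at its brightest probe set, and turned to 0.23 log2 in favour of CD4 when probe sets shared between transcripts were left out, where DKK3 and ME1 lay under 2-fold. With the mean over probe sets, ME1, S100B and PLCG2 lay under 2-fold, LYZ was 6.19-fold, CYP1B1 4.10-fold and CYSLTR1 5.40-fold higher on CD4, and DKK3 was 3.67-fold, DBN1 4.40-fold and TMT1A 3.08-fold higher on CD8. PLA2G7, MPEG1 and PLCG2 lay under 2-fold at the 65th-percentile floor.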

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

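Of the tests below, the one on the position of DN between CD4 and CD8 was set out before its result was seen, and all the others were chosen after it. Among 5182 measured probe sets that carry no single gene name and enter no comparison of the report, 50 were at least 2-fold higher on DN than on both others and 61 at least 2-fold lower, against 25 higher on CD4 and 17 higher on CD8 than on the other arrays. They were singled out because these data were not otherwise used. No simulated unchanged count was made for them, nor counts lower on CD4 or on CD8, so they were not separated from array error.

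DN lay nearer to CD8 than to CD4 at 71.4% of the genes higher on CD8. CD8 T cells that passed the sort would place DN at the same position between CD4 (0%) and CD8 (100%) for all these genes, and CD8A and CD8B lay at 23.0% and 20.3% on the linear scale. The median position of the 283 genes was 63.2% (bootstrap 95% interval 57.8% to 75.6%), with quartiles of 30.3% and 118.7%. The interval covers the number of genes only, not the spread between arrays or sorts. Beyond the CD8 array lay 84 genes, and 28 lay at or below the CD4 level. These positions argue against such cells as the whole cause. A share of them up to about the position of CD8A stays open, since CD8A was above the CD4 level. CD8B was above that level only at probe sets shared between transcripts. A hypothesis is that DN cells share much of the CD8 programme without its full cytotoxic part, and the mix of donors and cell subsets in each pool remains untested.

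Innate-like T genes were higher on DN than on CD8, with a median of 0.71 log2, but only 5 of 17 passed 2-fold (4 at a floor of 5.20). Of genes known from innate-like T cells, KLRB1 stood at 0.74 and RORA at -0.27 against CD8, both under 2-fold. ZBTB16 was higher by at least 0.24 when taken from 5.20, so it was barely above background on DN. NK cells would raise NK receptors too, and their median against CD8 was -0.61 (percentile 0) but -0.13 without shared probe sets. Of 7 NK-cell markers (median 0.28), FCER1G, IL18RAP and TYROBP lay above CD8 and KLRF1 and NCAM1 below it, at -0.61 and by at least 0.59, so NK cells cannot be told apart from a difference within T cells. Myeloid cells would raise the innate-like genes on CD4 over CD8, where the monocyte list was higher, but CD8 T cells express these genes themselves, so their median there of -0.63 does not test this and myeloid cells stay open too. A higher share of MAIT or other innate-like cells among DN cells may underlie the pattern, with NK and myeloid cells still open, as a hypothesis found and examined on the same arrays, on which the 5′ loss of DN was not tested.

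Markers of myeloid and B cells were higher on DN, although a sort for the alpha-beta T cell receptor would remove those cells. Monocyte markers had a median of 1.14 against CD8 (0.46 at a floor of 5.20), with LYZ at log2 11.50 and S100A8 at 9.21 on DN, but the abundant monocyte genes S100A9 and CST3 stood at 4.34 and 4.37, near the floor on all 3 arrays, where it is not known whether their probe sets respond, so myeloid cells cannot be told apart from expression in T cells. Of B-cell markers, 4 were at least 2-fold higher than on CD4 (2 at a floor of 5.20), with IGHM at 9.30 and MS4A1 at 9.96. MS4A1 also stood at 8.64 on CD8. Among other genes of the B-cell lineage, POU2AF1 stood at 11.01 and JCHAIN at 7.57 on DN. CD79B stood at 5.92 on DN and 6.08 on both others, and CD79A, IGKC, IGHD, BLNK and FCER2 lay under 5.20 on all 3 arrays. The low values of CD79B and these 5 genes go against B cells. As the response of their probe sets is not known either, B cells stay open. Over 1847 dim genes, DN minus CD8 had a median of 0 and an upper quartile of 0.28 log2. That quartile lay under both monocyte medians but above the B-cell median of 0.25 against CD8. As values under the floor were raised to it and many values are identical between arrays, such differences are drawn towards 0. A general lift of dim probe sets on DN is therefore not decided by these values. No biological explanation of these markers was tested.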

How the results depend on the processing

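Of the alternatives, the restriction to genes with several agreeing probe sets was chosen after the data were seen, and all planned ones were run. Quantile normalization and centring on the median moved no result past its limits (1.5 times for a count, the disagreement between probe sets for a difference). As the medians and quartiles of the arrays were already close when deposited, these alternatives had little to change. Over all alternatives, 688 values of single genes stayed within those limits, 370 moved in size and 1 changed sign, and for lists 671 stayed, 48 moved and 1 changed sign. TMT1A (CD4 minus CD8) turned to 0.23 and the type 2 list (CD4 minus CD8) to -0.023 without probe sets ending in _x_at, _s_at or _a_at. The stricter 65th-percentile floor gave 116 genes higher and 42 lower on DN than on both others, 101 lower on CD4 than on both and 25 lower on CD8 than on both. Per pair it gave 267 higher on DN than on CD4, 164 higher than on CD8, 102 higher on CD4 than on CD8 and 186 lower. The mean over probe sets gave 115 higher on DN than on both, 50 higher and 89 lower on CD4, 39 higher and 28 lower on CD8, and per pair 254 (DN over CD4), 162 (DN over CD8), 95 (CD4 over CD8) and 171 (CD8 over CD4). With log2(value + floor), 39 genes were lower on DN than on both, 33 higher and 39 lower on CD8 than on both, and 104 lower on DN than on CD8. At 3-fold, 100 genes were higher and 14 lower on DN than on both, 27 higher and 53 lower on CD4, and 11 higher and 20 lower on CD8. Per pair the 3-fold counts were 208 higher and 64 lower on DN than on CD4, 136 and 41 against CD8, and 63 higher and 94 lower on CD4 than on CD8. Genes with 2 or more probe sets above the floor that all passed 2-fold numbered 27 higher and 6 lower on DN, 14 and 16 on CD4, and 8 and 5 on CD8, which follows in part from the fewer genes with several probe sets. DN lay nearer CD8 at 80.9% of genes at 3-fold and 64.3% with the mean over probe sets, and nearer CD4 at 32.4% with the 65th-percentile floor. For CD4 minus CD8, the 25th-percentile floor and the removal of floor and filter each gave list medians of 1.14 (CD4 lineage), -1.76 (NK receptors) and 0.54 (monocyte). Both gave 1.52 for monocyte markers, DN minus CD8. Without shared probe sets the medians were -1.94 (CD8 lineage, CD4 minus CD8) and, for NK receptors, -0.76 (CD4 minus CD8), 0.83 (DN minus CD4) and -0.13 (DN minus CD8). The 65th-percentile floor gave 0.80 for CD8 lineage (DN minus CD4), 1.497 and 0.62 for B-cell markers (DN minus CD4 and minus CD8) and 0.48 for monocyte markers (DN minus CD8). The silent-reference floor gave 0.46 for monocyte markers in both comparisons of DN. The mean over probe sets gave 0.41 for monocyte markers (DN minus CD4) and 0.0044 for CD4 lineage (DN minus CD8). The CD4 transcript, CD4 minus CD8, was 4.48 at the 65th-percentile floor, 5.27 at the silent-reference floor, 4.995 with log2(value + floor) and 2.13 with the mean. DN minus CD4 it was -4.48, -4.52 with log2(value + floor) and -2.13 with the mean, and DN minus CD8 it was 0 at the 65th-percentile floor and with the mean, and 0.21 at the silent-reference floor. CD8B, CD4 minus CD8, was -4.43 with log2(value + floor), -3.34 with the mean and -2.40 without shared probe sets, and DN minus CD4 it was 1.45 with the mean and 0 without shared probe sets. The higher floors compress differences of single genes by construction. The B-cell medians instead rose at the 65th-percentile floor, from 0.25 in both comparisons of DN. There, dim markers such as CD79A no longer counted as measured, so the median was taken over fewer, brighter markers. Moves with the mean over probe sets can come from probe sets under the floor, which it includes. The causes of the other moves were not tested. Some named genes gave no value at the 65th-percentile floor, with the mean or without shared probe sets, the platelet list gave none at the 65th-percentile and silent-reference floors, and the gamma-delta list none without shared probe sets. No paired analysis was possible because each group has 1 array and the groups share only a number given in accession order, and for the same reason no replicate could be left out. Signal near the floor limits the dim genes, and on DN the 5′ loss limits probe sets far from the 3′ end.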

Other observations

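Several gene groups not described above were close on the 3 arrays or moved in few members. Of 13 cell cycle genes, none passed 2-fold between DN and either other array, with medians of 0 against CD4 (percentile 32.7) and 0.09 against CD8 (percentile 85.4), and TOP2A, a topoisomerase of dividing cells, was 1.04 log2 higher on CD4 than on CD8. Interferon response genes were slightly lower on DN, with medians of -0.18 against CD4 (percentile 0.62) and -0.25 against CD8 (percentile 0.15), and RSAD2 was the one of 14 past 2-fold, at -1.24 against CD8. Of 15 TCR signalling genes, none passed 2-fold on DN (medians 0.16 and 0.01), while the phosphatase PTPN22 and the adaptor SLA2 were lower on CD4 than on CD8, at -1.12 and -1.06. Ribosomal protein genes were slightly lower on DN, with medians of -0.32 against CD4 (percentile 0.075) and -0.16 against CD8 (percentile 1.46), and RPL11 was the one of 15 past 2-fold, at -1.16 against CD4. For CD4 minus CD8, their median of 0.05 already reached percentile 98.1, so an extreme percentile is no measure of size. None of 12 oxidative phosphorylation genes passed 2-fold in any comparison, with medians of -0.16 and -0.20 on DN. Of 14 apoptosis genes, the death ligand TNFSF10 stood at -1.42 against CD4 and FASLG, another death ligand, at -1.17 against CD8. None of 4 type 2 genes, including GATA3 at 0.27 against both, passed 2-fold in any comparison. Of 11 activation and class II genes, HLA-DMA was higher on DN than on CD4 by 1.29 and ICOS lower, and none passed 2-fold against CD8.

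Type 1 genes split by comparison. Of 8 measured, 2 were higher on DN than on CD4, HAVCR2 and the chemokine CCL4 at 1.13, and against CD8 HAVCR2 was higher and TBX21, the master factor of type 1 cells, lower at -1.09. Of 16 homing receptors, 2 were higher and 1 lower on DN than on CD4, and 2 higher and 3 lower than on CD8. CXCR5, the receptor that leads cells to B-cell follicles, was at least 1.99 log2 higher than on CD8, while ITGAM lay at -1.29 and -1.86 and CX3CR1 at -1.30 against CD8. Of 15 cytokines and chemokines, 4 were higher and 1 lower against CD4, and 2 higher and 2 lower against CD8, with CXCL8 past 2-fold at the lower floor only (3 and 1 higher at a floor of 5.20) and TGFB1 at -1.43 against CD8. Of 12 inhibitory receptors and anergy genes, 3 were higher and 2 lower against CD8 (median 0.15), with the ubiquitin ligase ITCH at -1.67. Of 19 naive and central memory genes, MYB and PECAM1 were the only ones past 2-fold on DN against CD4 and MYB against CD8 (medians -0.14 and 0.07). Of 3 measured genes of the gamma-delta list, TRDV3 was higher on DN than on CD4 by 1.13, and SOX13 and TARP were lower than on CD8, at -1.53 and -1.25. Of 7 measured genes of the reference silent in blood, CYP2E1 was higher on DN, by 3.15 and 1.87, and the others lay within 2-fold. The ribosomal RNA control for 28S stood at log2 8.54 on DN and 7.35 on both other arrays, and that for 18S at 11.97, 11.44 and 11.60 on DN, CD4 and CD8.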
